A study of Arabidopsis thaliana with 11 samples.

How the data were processed

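RNA from sorted root cells of Arabidopsis seedlings was measured on 11 Affymetrix arrays. Cortex cells came from the fluorescent marker line J1551 and pericycle cells from the line J2731. Roots were digested for 30 min to release protoplasts, the fluorescent protoplasts were collected by flow sorting, and their RNA was amplified and biotin-labelled with a kit for small inputs. Per the labels, the seedlings of a tank made up a biological sample, so the replicates are separate tanks. Seedlings were 7 days old at harvest. Salt-treated seedlings had 5 days of growth without salt and 2 days with it, at 25 mM NaCl with 0.22 mM CaCl2 on the first of these days and 50 mM NaCl with 0.375 mM CaCl2 on the next.

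The authors deposited a table of log2 expression values, with 22810 probe sets on each array. Their processing notes name RMA and limma, without versions; the role of each tool is not given in the sources used here. The log2 scale was read from the values, which run from about 1 to about 13 on every array with medians of 3.41 to 3.58. These minima and medians look low for default RMA, so how the values near the floor were made is uncertain, and with it the dim limit given below and folds near it. No detection calls were used here. Probe sets with a mean under 2.81, the 40th percentile of all probe sets, are called dim, and fold differences of genes with a group near that level can understate the change. Arrays give no read depth, so their number, 2 or 3 per group, limits the precision. The values were used as deposited, with no further normalization. The 64 array control probe sets were left out, which left 22746 probe sets in every test.

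Probe sets took their gene from the probe table used here. Of the tested probe sets, 13513 had exactly 1 gene, 503 had several genes and were not named, and 8730 had no gene in that table. Of those with 1 gene, 13436 were matched by gene identifier to RefSeq annotation of assembly TAIR10.1, which gave the symbols; genes without a symbol are named by locus code. No coordinates are printed, because the deposited values name no genome build. The sodium transport genes HKT1, SOS1, NHX1 and AVP1 were to be named in both salt comparisons, but 0 probe sets were paired with them in the annotation used, so their values are not reported.

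All 11 arrays were fitted together in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit, eBayes without trend and not robust) with a mean per group, so that every comparison used the same estimate of spread, with 7 residual and 2.96 prior degrees of freedom. The comparisons were salt minus control in cortex, salt minus control in pericycle, the difference of these responses (pericycle minus cortex), and pericycle minus cortex under control conditions and under salt. P values are two-sided and were adjusted by the Benjamini-Hochberg method within a comparison, and a probe set passed at an adjusted p under 0.05 with no fold limit. Errors of log2 differences are limma standard errors. The replicate numbers were not used to pair arrays, as the labels do not tie numbers across groups. Residuals of arrays with the same number correlated between -0.0646 and 0.107 across groups.

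Gene lists were tested with camera in limma at the preset correlation between genes of 0.01 and, as an alternative, with an estimated correlation. A gene was represented by its probe set with the highest mean, and the background was built the same way. The design, the limma and camera tests, the rule for named genes, the lists of marker and pathway genes called fixed below and all alternatives except testing the fixed lists alone were chosen before the data were examined. Some tests of explanations were chosen after the results were seen and are named as such below. Because the annotation names few of the planned genes, further lists, called added below, were written from the names it holds after the files were seen and before any test. Of the lists with 3 or more measured genes, 37 were tested together, and 5 of these were fixed lists. Values were also kept for lists with fewer genes, 49 lists in all, and 6 fixed lists had no measured gene. In each comparison the named genes are the 8 with the largest positive and the 8 with the largest negative log2 difference among those that passed, had exactly 1 gene and had every array of a group above every array of the other (not asked for the difference of responses), and up to 4 members of a list that passed. Up to 2 members were given as values where none passed.

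The procedure was tested on simulated data of the same size with 200 changed probe sets, 100 of them at a log2 difference of 1 and 100 at 2. With equal spread in all groups it recovered 33% and 79% of these for salt in cortex (8 of 120 calls false), 24% and 70% for salt in pericycle (4 of 98), 7% and 47% for the difference of responses (5 of 59), 24% and 76% for the cell types under control conditions (7 of 107) and 35% and 80% under salt (2 of 117). In another setting, the pooled spread of each probe set was scaled by 1 factor per group, taken from the group's median variance. It then recovered in the same order 48% and 89% (1 of 138 false), 46% and 82% (50 of 178), 24% and 74% (16 of 114), 39% and 80% (6 of 125) and 52% and 83% (37 of 172).

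Alternatives were leaving out dim probe sets, quantile normalization, subtracting array medians, eBayes with trend and robust set, array weights, fitting only the groups compared, asking for a log2 difference of at least 1, using 1 probe set per gene, a replicate block, leaving out each array in turn and, for lists, an estimated correlation, the mean over a gene's probe sets and the fixed lists alone. The last was chosen after seeing the data.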

Results

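Expression was measured in flow-sorted root cells of 7-day-old Arabidopsis seedlings, with 3 arrays for cortex cells without salt, 3 for cortex cells with salt, 2 for pericycle cells without salt and 3 for pericycle cells with salt. The cortex is the ground tissue outside the endodermis, and the pericycle is the outermost layer of the central cylinder, from which lateral roots arise. Correlations between arrays of a group were 0.987 to 0.99 in cortex control, 0.993 to 0.994 in cortex salt, 0.947 in pericycle control and 0.917 to 0.966 in pericycle salt samples. The median SD of a probe set was 0.181, 0.139, 0.25 and 0.365 in the same order, so the pericycle samples varied more than the cortex samples. The array of pericycle salt replicate 1 stood apart, with an array weight of 0.171 and correlations of 0.917 and 0.919 with the other arrays of its group. Its ubiquitin and GAPDH 3' minus 5' differences, a sign of RNA quality, were 2.92 and 0.995. The group means of the GAPDH difference were 0.64 ± 0.0834 (SD, n = 3) in cortex control, 0.78 ± 0.0873 (n = 3) in cortex salt, 0.40 ± 0.164 (n = 2) in pericycle control and 0.70 ± 0.265 (n = 3) in pericycle salt samples. The first principal component held 49.8% of the variance and separated the cell types. A fixed list of cortex markers had 4 measured genes, none of which passed in any comparison. The list mean was 2.60 and 2.59 in cortex samples without and with salt, under the dim limit. In pericycle samples it was 3.06 and 2.96. At these levels the list cannot show whether the sorted cells were cortex cells, so their identity rests on the marker line. The mean of 12 added markers of root hairs, which are not of either sorted type, was higher. It was 6.04 ± 0.2 (SD, n = 3) in cortex control and 5.06 ± 0.33 (n = 2) in pericycle control samples. The purity of the sorted cells was not measured. The list median was 0.43 higher in pericycle than in cortex under control conditions (adjusted p = 0.27). Under salt it was 0.23 higher (adjusted p = 0.354), and no shift with salt was called in either cell type.

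The first comparison asked how cortex cells responded to salt. PAP20, a purple acid phosphatase, rose by 3.24 ± 0.318 (log2, SE; n = 3 and 3; adjusted p = 4.84e-04), from 3.55 to 6.80. The peroxidase gene AT5G15180 fell by 4.62 ± 0.243, or 24.6-fold (adjusted p = 2.15e-05). Of 8 measured genes of cell wall expansion, 3 fell and 5 did not pass (list adjusted p = 0.229 with an estimated correlation). Those that fell included the beta-expansin gene EXPB1, by 2.06 ± 0.401 (adjusted p = 0.0195), and XTH18, a xyloglucan endotransglucosylase gene, by 1.56 ± 0.331 (adjusted p = 0.0282). At the preset correlation, cytosolic ribosomal proteins stood higher as a group (7 of 120 genes passed; adjusted p = 0.274 with an estimated correlation) and root hair markers stood lower (2 of 12 passed; adjusted p = 0.173 with an estimated correlation).

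Of the 22746 probe sets tested, 946 changed with salt in cortex cells, 326 upward and 620 downward, with a median absolute log2 difference of 1.41. Exactly 1 gene was given for 491 of them. The others with the largest rises by the rule for named genes were AT5G38030 (3.21), AT5G07330 (2.64), AT1G15330 (2.37), AT2G34020 (2.19), AT4G38410 (2.13), AT5G01870 (2.13) and AT5G59080 (2.07). Those with the largest falls were AT3G21340 (-3.60), AT3G23090 (-3.58), AT5G48290 (-3.50), AT5G02890 (-3.43), AT5G01210 (-3.35), AT3G51330 (-3.33) and AT2G43150 (-3.32). In all of these named genes, as the rule for naming them asks, the 3 salt arrays lay on the same side of the 3 control arrays.

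The fixed list of cell wall expansion had 8 measured genes with a median of -1.04 (adjusted p = 7.07e-05; adjusted p = 0.229 with an estimated correlation). EXPB1, XTH18 and COB, a gene of oriented cell expansion (-0.83 ± 0.189), fell, none rose and 5 did not pass; adjusted over the list alone, 6 fell. Of its genes, 7 are also in the added list of expansins and xyloglucan endotransglucosylases, where 3 of 28 fell, among them XTH33 by 2.35 ± 0.414 (list median -0.24, adjusted p = 4.06e-04; adjusted p = 0.229 with an estimated correlation). Of 120 cytosolic ribosomal protein genes, 7 rose and none fell, and the median was 0.68 (adjusted p = 2.77e-20; adjusted p = 0.274 with an estimated correlation). AT1G80750 rose by 2.01 ± 0.292, AT2G44120 by 1.16 ± 0.226 and AT5G23900 by 1.05 ± 0.2. The mean of the list was 6.65 ± 0.155 (SD, n = 3) without salt and 7.29 ± 0.0364 (n = 3) with salt, and the GAPDH 3' minus 5' difference was also higher in the salt samples, as given above.

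Of 55 class III peroxidase genes, which act in cell wall cross-linking and reactive oxygen metabolism, 9 fell and none rose (median -0.14, mean -0.58, adjusted p = 8.98e-06; adjusted p = 0.173 with an estimated correlation). Besides AT5G15180 these included AT3G01190 (-3.07 ± 0.528), AT5G17820 (-2.76 ± 0.537) and AT4G30170 (-2.43 ± 0.308). Markers of root hairs, which are cells of the epidermis and not of the sorted type, moved with salt: the median of 12 added root hair markers was -1.71 (adjusted p = 1.18e-09; adjusted p = 0.173 with an estimated correlation). Of these, AT4G08410 fell by 2.1 ± 0.285 and AT1G30870 by 1.65 ± 0.398, and 10 did not pass. The root hair list shares 4 genes with the peroxidases, 2 with the cell wall expansion list and 3 with the expansins and xyloglucan endotransglucosylases. Among the 51 peroxidase genes outside the root hair list, 8 fell.

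Further added families shifted at the preset correlation. Of 22 TBL genes, related to acetylation of wall polysaccharides, TBL38 (-2.87 ± 0.317), TBL41 (-2.83 ± 0.334) and TBL34 (-0.82 ± 0.184) fell (median -0.12, adjusted p = 3.85e-03; adjusted p = 0.173 with an estimated correlation). Of 15 GH9 endoglucanase genes, GH9C1 (-2.02 ± 0.401) and GH9C2 (-0.97 ± 0.188) fell (median -0.26, adjusted p = 0.0118; adjusted p = 0.274 with an estimated correlation). Of 15 tetraspanin genes, TET6 (-1.51 ± 0.354) and TET8 (-1.51 ± 0.155) fell (median -0.21, adjusted p = 8.96e-03; adjusted p = 0.173 with an estimated correlation). The 69 plastid-encoded genes had a median of -0.29 without any single gene passing (adjusted p = 1.16e-03; adjusted p = 0.816 with an estimated correlation). The fixed list of proteins induced by abscisic acid and water deficit did not shift (4 genes, median -0.05, adjusted p = 0.319). None of its genes passed, and adjusted over the list alone 1 fell, COR47, which differed by -0.46 (adjusted p = 0.0964 over all probe sets). The other fixed lists tested, auxin and lateral root initiation (4 genes, median -0.13, adjusted p = 0.358) and reactive oxygen metabolism (3 genes, median -0.06, adjusted p = 0.834), had no gene that passed, over all probe sets or adjusted over the list alone. Single genes rose in lists that did not shift, among them DI21 (1.24 ± 0.147) and M10 (1.51 ± 0.241) of the water-deficit and late embryogenesis proteins and JRG21, a jasmonate-regulated gene (1.91 ± 0.345).

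The count for cortex depends on the spread used: with only the cortex arrays fitted it was 4487, of which 57.5% rose, and without a single array it ran from 362 (cortex salt replicate 3 left out) to 1701 (pericycle salt replicate 1 left out). EXPB1, XTH18, XTH33, COB, GH9C1, GH9C2, TET6, JRG21, AT1G30870, AT2G44120, AT5G23900, AT3G01190, AT5G17820, AT4G38410, AT5G01870, AT3G51330 and TBL34 each missed the threshold without at least 1 of the cortex arrays, while PAP20, AT5G15180, AT1G80750, AT4G30170, AT4G08410, TBL38, TBL41, TET8, DI21 and M10 passed whichever single array was left out.

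The next comparison asked how pericycle cells responded to the same salt treatment. IAA29, an auxin-response repressor gene, fell by 4.09 ± 0.45, or 17-fold (log2, SE; n = 2 and 3; adjusted p = 6.00e-03), from 7.10 to 3.01. BGLU40, a beta-glucosidase gene, rose by 2.63 ± 0.343 (adjusted p = 9.87e-03) and AT2G41810 by 3.52 ± 0.468 (adjusted p = 0.0102). PSY1R, a receptor kinase gene for a growth-promoting peptide, fell by 2.81 ± 0.323 (adjusted p = 6.87e-03). These calls rest on a spread shared with the cortex arrays: with only the pericycle arrays fitted, limma called 0 probe sets, with 1502 at an unadjusted p under 0.05, and with array weights it called 32.

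With all arrays fitted, 453 probe sets changed with salt in pericycle cells, 237 upward and 216 downward, with a median absolute log2 difference of 1.51. The other named rises were AT1G53530 (3.00), AT5G53150 (2.62), AT5G11010 (2.61), AT3G12340 (2.56), AT5G37840 (2.53) and AT1G79470 (2.45). The other named falls were AT3G52900 (-3.30), AT1G67510 (-3.02), AT1G09440 (-2.84), ORA47 (-2.64), AT4G11210 (-2.63) and AT4G08160 (-2.60). ORA47 is a transcription factor gene of the jasmonate pathway. As the rule for named genes asks, the salt arrays lay on the same side of both control arrays in each of these named genes. BGLU40, AT3G52900, AT1G67510 and AT4G11210 also passed with array weights.

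Among the gene lists, the 12 root hair markers had a median of -1.24 in pericycle samples (adjusted p = 7.89e-04; adjusted p = 0.589 with an estimated correlation), and AT4G08410 fell by 1.55 ± 0.318. OPS, the only phloem marker measured, differed by 1.1 ± 0.363 and did not pass (adjusted p = 0.17). It passed over the list alone, which for a single gene is no adjustment. Of 22 TBL genes, TBL34 fell by 1.87 ± 0.206 (median -0.42, adjusted p = 2.33e-03; adjusted p = 0.168 with an estimated correlation). Of 7 calmodulin-like genes, CML42 rose by 1.68 ± 0.3 (median 0.71, adjusted p = 0.0341; adjusted p = 0.374 with an estimated correlation). The 69 plastid-encoded genes had a median of 0.32 with no single gene passing (adjusted p = 7.89e-04; adjusted p = 0.961 with an estimated correlation), and this median was -0.01 without pericycle control replicate 1. The cell wall expansion list did not shift (median -0.20, adjusted p = 0.941), nor did the abscisic acid and water-deficit list (median 0.02, adjusted p = 0.941) or reactive oxygen metabolism (median 0.22, adjusted p = 0.941). None of their genes passed, over all probe sets or adjusted over the list alone. In the auxin list, IAA29 fell in both counts and the list did not shift (median -0.17, adjusted p = 0.209). Other genes that passed were LEA4-5, a late embryogenesis abundant protein gene (1.5 ± 0.313), GH9C2 (1.83 ± 0.21), PUB22, a ubiquitin ligase gene (1.09 ± 0.202), XTH16 (-1.75 ± 0.344) and ATG8C, an autophagy gene (-0.94 ± 0.182).

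Without a single array the count ran from 183 (without cortex salt replicate 2 or 3) to 1124 (without pericycle control replicate 1), it was 975 without pericycle salt replicate 1, the array that stood apart, and the calmodulin-like list was not called with array weights, without dim probe sets, or without pericycle control replicate 1 or 2 or pericycle salt replicate 1 or 3. None of the other 3 lists was called without pericycle control replicate 1, nor were the TBL genes without dim probe sets or the plastid-encoded genes without pericycle salt replicate 2. In simulated data with the pooled spread scaled by 1 factor per group, 50 of the 178 calls in this comparison were false. That setting tends to give too little spread, so this share cannot be carried over to the real calls.

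**Figure D1:**
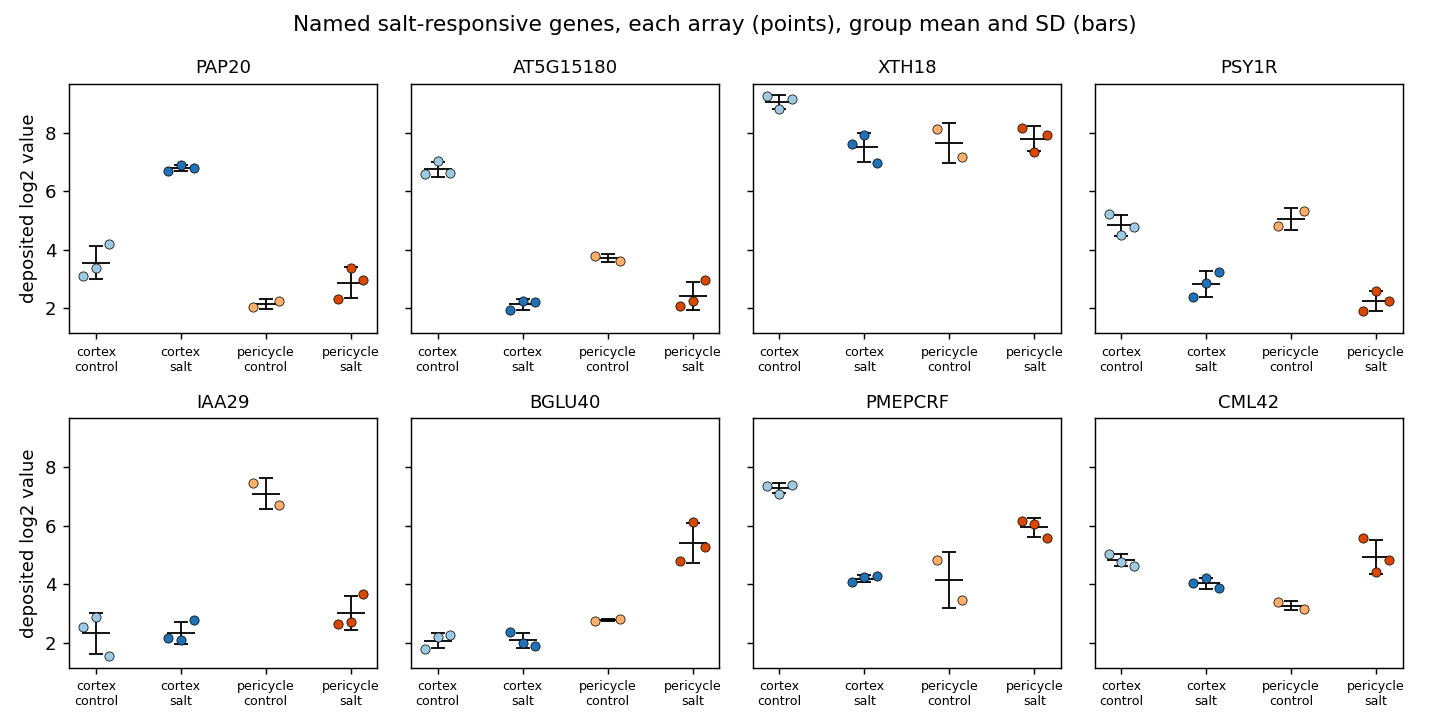
Deposited log2 values of 8 named genes on each array (points), with the group mean and SD (bars), for cortex and pericycle samples without and with salt. AT5G15180 falls in cortex from 6.74 to 2.12, and IAA29 falls in pericycle from 7.10 to 3.01 while it stays at 2.32 and 2.34 in cortex.

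The overlap and the difference of both responses were then tested. Of the probe sets that changed, 30 rose and 43 fell in both cell types, where 3.4 and 5.89 would be expected of independent lists. Both comparisons took the same spread for a probe set, so the lists are not fully independent even without a shared response. Genes that fell in both included PSY1R (-2.01 ± 0.289 in cortex) and AT3G13610 (-2.28 ± 0.279 in cortex and -2.30 ± 0.312 in pericycle). AER, an alkenal reductase gene (1.63 ± 0.334 and 2.27 ± 0.374), and AT3G48460 (1.69 ± 0.271 and 2.35 ± 0.303) rose in both. These genes of the overlap were chosen after their values were seen, except PSY1R, which the rule names in pericycle. Across probe sets, which are not independent replicates, the responses correlated with r = 0.244, and 73.7% of the cortex calls had the same sign in pericycle.

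The response differed between the cell types for 190 probe sets (134 more positive and 56 more negative in pericycle). The balance of directions depended on single arrays: it was 293 and 242 without pericycle salt replicate 3. It was also near even without either pericycle control array, a fit that leaves 1 array in that group. Leaving out any 1 of the cortex arrays moved it the other way, up to 47 and 6 without cortex salt replicate 3. PMEPCRF, a pectin methylesterase gene, differed most among named genes, by 4.89 ± 0.466 (log2, SE; adjusted p = 3.00e-03): it fell by 3.09 ± 0.311 in cortex and rose by 1.8 ± 0.347 in pericycle. GH9C2 likewise fell in cortex and rose in pericycle (difference 2.80 ± 0.282, adjusted p = 3.58e-03). Both were among 5 probe sets called in opposite directions, where 9.56 would be expected of independent lists; the others were AT4G23730, AT2G01300 and a probe set without a gene in the table used, each lower in cortex and higher in pericycle and chosen after their values were seen. IAA29 had a difference of -4.11 ± 0.604 (adjusted p = 0.0169), and its cortex level was near background in both conditions. UGT71C1, a glycosyltransferase gene, fell in cortex by 2.11 ± 0.166 and had a difference of 2.28 ± 0.249 (adjusted p = 4.19e-03). CML42 had a difference of 2.46 ± 0.402 (adjusted p = 0.0269).

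The cell wall expansion list differed between the responses (median 1.03, adjusted p = 7.17e-03; adjusted p = 0.753 with an estimated correlation), with no gene that passed over all probe sets and 2 when adjusted over the list alone. The peroxidases (median 0.22, adjusted p = 7.17e-03; adjusted p = 0.753 with an estimated correlation), the ribosomal proteins (median -0.52, adjusted p = 1.21e-06; adjusted p = 0.81 with an estimated correlation) and the plastid-encoded genes (median 0.65, adjusted p = 1.01e-07; adjusted p = 0.81 with an estimated correlation) differed as well. For the root hair markers no difference between the responses was detected (median 0.51, adjusted p = 0.262). Without a single array the count of probe sets ran from 53 (without cortex salt replicate 3) to 635 (without pericycle control replicate 1), and the cell wall list was not called with array weights or without pericycle control replicate 2. Without pericycle control replicate 1 the peroxidases and the plastid-encoded genes (median 0.21) were not called, and without pericycle salt replicate 1 the peroxidases (median 0.04) and the ribosomal proteins (median -0.16) were not called. PMEPCRF, GH9C2, UGT71C1, AT5G15180, AT3G18560, AT5G38030 and AT1G67510 passed under every alternative run. AT5G15180 also fell in pericycle, by 1.28 ± 0.272 (adjusted p = 0.0456), and ended under the dim limit of 2.81 in both cell types (2.12 in cortex and 2.42 in pericycle), from a lower start in pericycle (3.70) than in cortex (6.74), so the floor bounds its difference. UGT71C1 was at 3.05 and 3.21 in pericycle and AT1G67510 at 2.62 and 2.15 in cortex, without and with salt, which also left little room to fall.

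**Figure D2:**
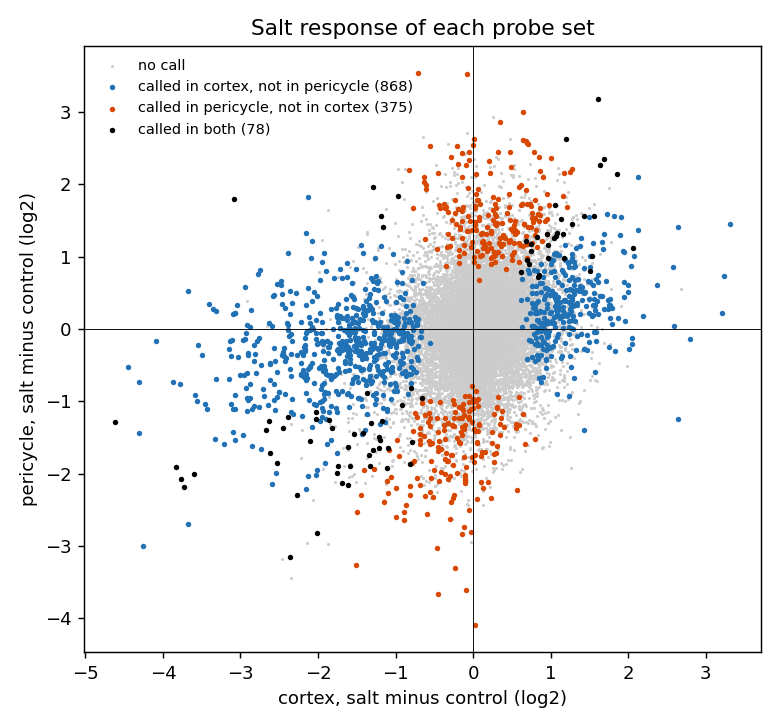
Salt response of each of the 22746 probe sets, as the log2 difference in cortex (horizontal axis) against that in pericycle (vertical axis), coloured by the comparison in which it passed. Most probe sets called in both cell types lie in the quadrants of the same sign, 30 upward and 43 downward, and 5 lie in the quadrants of opposite sign.

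Pericycle and cortex cells without salt were compared next, for which the samples differ in both cell type and marker line. AT2G27740 was higher in pericycle by 6.33 ± 0.347, or 80.2-fold (log2, SE; n = 2 and 3; adjusted p = 1.31e-05). Of 22 genes written for auxin response and lateral root initiation, 4 were measured and 2 of these passed (list adjusted p = 0.187 with an estimated correlation). They were IAA29, higher by 4.78 ± 0.45 (adjusted p = 1.28e-04), and LBD16, a transcription factor gene of lateral root initiation, higher by 3.89 ± 0.302 (adjusted p = 4.93e-05). SWEET2, a sugar transporter gene, was lower in pericycle by -4.35 ± 0.604 (adjusted p = 1.15e-03). Of 69 plastid-encoded transcripts, 40 were higher in the pericycle samples (list adjusted p = 0.457 with an estimated correlation).

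Of the probe sets, 3387 differed, 1527 higher and 1860 lower in pericycle. The other named genes higher in pericycle were AT2G25450 (5.63), MGL, a methionine gamma-lyase gene (5.27), the peroxidase gene AT5G51890 (5.20), AT5G45500 (5.10), AT4G15390 (4.92) and AT5G26330 (4.86). The others lower in pericycle were AT1G66760 (-4.13), AT5G47740 (-4.07), AT1G50060 (-4.07), CYP718 (-4.03), AT1G19900 (-4.00), scpl28 (-3.80) and AT1G51840 (-3.76). All of these named genes passed under every alternative run.

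The auxin and lateral root list was higher in pericycle (4 genes, 2 passing and 3 adjusted over the list alone; median 2.48, adjusted p = 9.28e-04; adjusted p = 0.187 with an estimated correlation). Of the 69 plastid-encoded genes, 40 were higher in pericycle and none lower (median 1.64, adjusted p = 1.26e-22; adjusted p = 0.457 with an estimated correlation), among them the photosystem genes psaA (2.37 ± 0.445) and psaB (2.34 ± 0.441). Of 16 mitochondrion-encoded genes, ccb206 (1.42 ± 0.395) and nad1 (0.71 ± 0.205) were higher (median 0.49, adjusted p = 0.0275; adjusted p = 0.893 with an estimated correlation). Of 120 ribosomal protein genes, 24 were higher and none lower, among them AT2G20450 by 2.05 ± 0.353 (median 0.69, adjusted p = 4.54e-11; adjusted p = 0.572 with an estimated correlation). Of 10 autophagy genes, 4 were lower, among them APG8A (-1.96 ± 0.394) and ATG8H (-1.63 ± 0.284; median -0.89, adjusted p = 0.0137; adjusted p = 0.361 with an estimated correlation). Of the root hair markers, AT1G30870 was lower by -1.64 ± 0.445 (median -1.07, adjusted p = 0.0402; adjusted p = 0.572 with an estimated correlation). The hybridisation spikes had means of 10.4 ± 0.223 (SD, n = 3) in cortex and 10.8 ± 0.27 (n = 2) in pericycle control samples.

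Single genes of short lists also differed: OPS, a phloem gene, was higher in pericycle by 1.67 ± 0.363, and HCT, a phenylpropanoid gene, by 2.09 ± 0.352. The fixed lists of cell wall expansion (median -0.20, adjusted p = 0.768; 1 gene higher and 2 lower, 2 and 3 when adjusted over the list alone), abscisic acid and water deficit (median 0.04, adjusted p = 0.924) and reactive oxygen metabolism (median -0.18, adjusted p = 0.992) did not shift, and none of the genes of the latter lists passed by either count. Without a single array, the count of probe sets ran from 2258 to 5007. Of 19 alternatives other than the estimated correlation, the root hair list was called in 12 (neither rescaling of the arrays among them), the autophagy list in 17 and the mitochondrion-encoded list in 14; the last was not called with array weights, where ccb206 and nad1 also missed the threshold.

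Under salt, pericycle and cortex cells were again far apart. AT3G28600 was higher in pericycle by 5.54 ± 0.344 (log2, SE; n = 3 and 3; adjusted p = 9.19e-06), and LBD16 by 4.37 ± 0.27 (adjusted p = 9.03e-06). The defensin-like genes LCR68 (5.26 ± 0.439) and LCR69 (5.24 ± 0.396) and the peroxidase gene Prx37 (5.02 ± 0.444) were higher as well. OSM34, an osmotin gene, was lower in pericycle by -3.99 ± 0.231 (adjusted p = 6.61e-06), and PAP20 by -3.93 ± 0.318.

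Of the probe sets, 4066 differed, 1764 higher and 2302 lower in pericycle. The other named genes higher in pericycle were AT2G25450 (5.39), AT5G49640 (5.35), AT5G45500 (5.17) and AT5G43180 (5.08). The others lower in pericycle were AT4G01240 (-4.71), AT1G51750 (-4.30), AT1G66860 (-4.28), scpl25 (-3.93), JAL33, a jacalin-related lectin gene (-3.92), and AT1G79770 (-3.87). Between the conditions, 1947 probe sets differed in the same direction in both (905 higher and 1042 lower in pericycle), where 306.7 would be expected of independent lists, and 24 in opposite directions. The spread of a probe set was shared by these comparisons too, so their lists are not fully independent.

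Of the 69 plastid-encoded genes, 58 were higher in pericycle under salt and none lower (median 2.32, adjusted p = 1.33e-37; adjusted p = 0.369 with an estimated correlation), among them psaB (3.50 ± 0.395) and psbH (3.08 ± 0.374). Of 23 nuclear photosynthesis genes, LHCB4.1 (2.85 ± 0.706) and TROL (2.04 ± 0.565) were higher (median 0.48, adjusted p = 0.0431; adjusted p = 0.59 with an estimated correlation). Of 16 mitochondrion-encoded genes, 3 were higher, with matR at 1.45 ± 0.302 (median 0.43, adjusted p = 8.02e-03; adjusted p = 0.59 with an estimated correlation). The hybridisation spikes had means of 10.3 ± 0.0712 in cortex and 10.9 ± 0.253 in pericycle salt samples (SD, n = 3 each).

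The auxin and lateral root list remained higher (median 1.56, adjusted p = 0.0105; adjusted p = 0.369 with an estimated correlation); LBD16 and the auxin-conjugating enzyme gene GH3.3 (2.45 ± 0.56) passed, over all probe sets and adjusted over the list alone. Of 28 expansin and xyloglucan endotransglucosylase genes, 8 were higher and 2 lower, with XTH20 at 4.18 ± 0.354 and EXPB1 at 2.46 ± 0.401 (median 0.29, adjusted p = 8.02e-03; adjusted p = 0.388 with an estimated correlation). Of the 55 peroxidases, 10 were higher and 4 lower (median 0.24, adjusted p = 0.039; adjusted p = 0.44 with an estimated correlation), with AT3G21770 at 4.57 ± 0.272. Of 5 xylem wall genes, AT1G79620 (3.59 ± 0.325) and IRX15-L (1.19 ± 0.213) were higher (median 0.49, adjusted p = 0.0448; adjusted p = 0.369 with an estimated correlation).

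Of 17 genes of endoplasmic reticulum stress and protein degradation, 5 were lower in pericycle, among them BZIP60 (-1.01 ± 0.257) and UBC32 (-1.21 ± 0.154; median -0.63, adjusted p = 8.02e-03; adjusted p = 0.369 with an estimated correlation). Of 10 autophagy genes, APG8A (-2.06 ± 0.352), APG8H (-2.05 ± 0.46) and ATG8C (-0.77 ± 0.162) were lower (median -0.64, adjusted p = 8.02e-03; adjusted p = 0.369 with an estimated correlation). The ribosomal protein median was 0.18 (4 higher of 120, adjusted p = 0.0378; adjusted p = 0.746 with an estimated correlation) and it was -0.03 without pericycle salt replicate 3. The fixed lists of cell wall expansion (median 0.41, adjusted p = 0.0863; 2 genes higher and 4 when adjusted over the list alone), abscisic acid and water deficit (median 0.14, adjusted p = 0.35; COR47 higher by 0.57 in both counts) and reactive oxygen metabolism (median 0.15, adjusted p = 0.641; GR1 higher by 0.81 in both counts) did not shift. Without a single array, the count of probe sets ran from 2461 (without cortex salt replicate 1) to 5102 (without pericycle salt replicate 3). Of 19 alternatives other than the estimated correlation, the peroxidase list was called in 13, the nuclear photosynthesis list in 15, the xylem wall list in 11 and the ribosomal list in 16. The mitochondrion-encoded list was not called without pericycle salt replicate 1, the auxin list not without pericycle salt replicate 3, and the lists of endoplasmic reticulum stress, expansins and autophagy not without dim probe sets. With only the groups compared GH3.3, LHCB4.1, TROL, BZIP60 and GR1 missed the threshold.

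**Figure D3:**
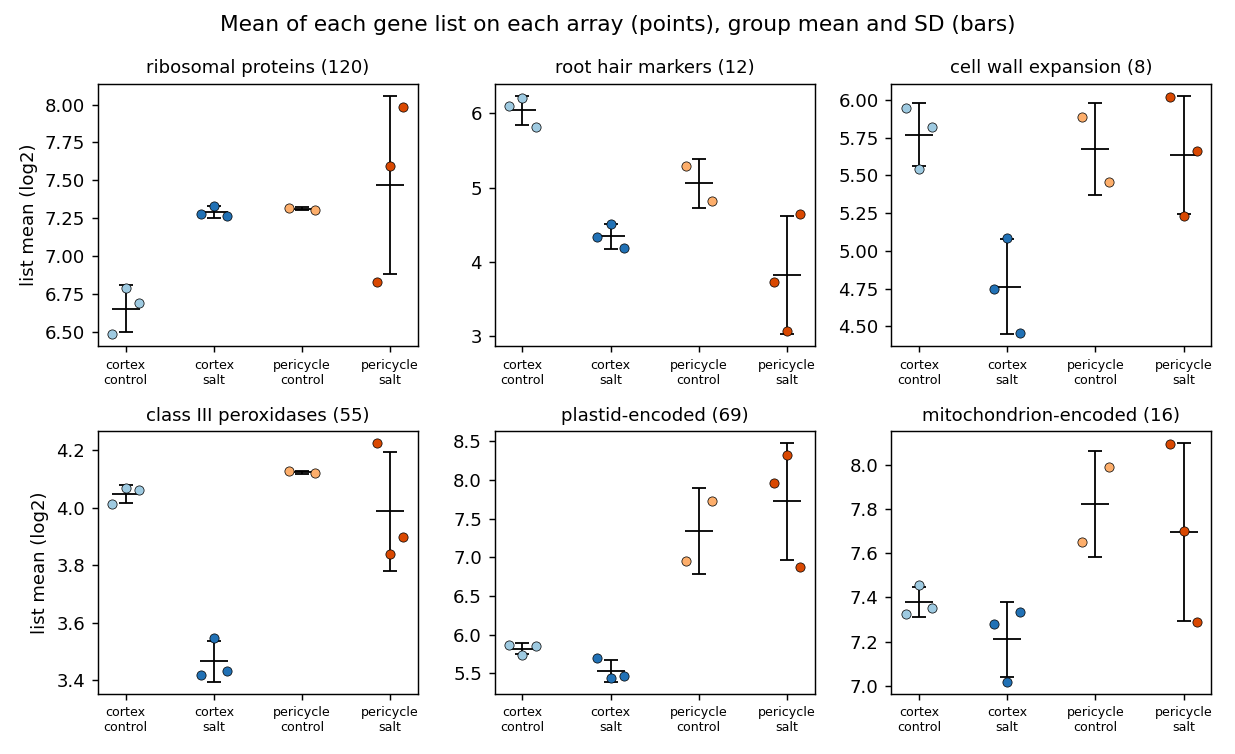
Mean log2 value of 6 gene lists on each array (points), with the group mean and SD (bars); the number of genes in a list is given in its title and each panel has its own scale. Plastid-encoded genes average 5.82 and 5.53 in cortex and 7.34 and 7.72 in pericycle samples, without and with salt.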

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

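The comparisons of the plastid-encoded genes with mitochondrion-encoded and nuclear photosynthesis genes and the test of equal falls among root hair markers were tests chosen only after the result was seen. The response to salt differed between pericycle and cortex, by the test of the difference itself, for 190 probe sets. By the same test, 4 gene lists differed at the preset correlation: cell wall expansion with a median of 1.03, ribosomal proteins with -0.52, peroxidases with 0.22 and plastid-encoded genes with 0.65 (log2, pericycle minus cortex). With an estimated correlation 0 lists were called (adjusted p = 0.753, 0.81, 0.753 and 0.81 in the same order). At the preset correlation, each list was lost in at least 1 alternative: the peroxidases and plastid-encoded genes were lost without pericycle control replicate 1, the peroxidases and ribosomal proteins without pericycle salt replicate 1, and the cell wall list without pericycle control replicate 2. The cell wall list was also lost with array weights.

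Among named genes the response was more positive in pericycle for PMEPCRF (4.89), AT5G19240 (3.95), AT5G01210 (3.63), AT2G41810 (3.59), AT5G55050 (3.56), AT3G16560 (3.48), AT3G18560 (3.37), AT5G15180 (3.34, a difference bounded by the floor, as it fell to under 2.81 in both cell types), GH9C2 (2.80), BGLU40 (2.62), TBL41 (2.61), CML42 (2.46), UGT71C1 (2.28), BGLU15 (2.05) and TET8 (1.35). It was more negative for IAA29 (-4.11), AT5G07330 (-3.89), AT3G52900 (-3.07), AT5G38030 (-2.99), AT2G27740 (-2.79), AT1G64490 (-2.74), AT1G67510 (-2.55), PAP20 (-2.51), AT1G80750 (-2.29), scpl48 (-1.53) and ATG8C (-1.26). IAA29 and AT1G67510 in cortex and UGT71C1 in pericycle were near the floor, as given above, and had little room to fall there.

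Plastid-encoded transcripts were higher in pericycle than in cortex samples by a median of 1.64 without salt (adjusted p = 0.457 with an estimated correlation). An equal log2 rise of all organelle RNA would not account for the whole of it: the difference between the cell types was larger for the plastid-encoded list mean than for the mitochondrion-encoded one by 1.07 ± 0.303 (SE) without salt and by 1.70 ± 0.271 with it. These errors pool all groups, although the pericycle list means varied more than those of cortex. An equal added amount of RNA cannot be decided this way. In cortex control samples the plastid-encoded mean was 5.82 and the mitochondrion-encoded one 7.38, so such an amount would raise the former more in log2. A scale difference with brightness is argued against too, since the median lay above all 10000 lists matched on expression (percentile 100; the upper bound of their central range was 0.04). RNA of green tissue cannot be told apart from a difference of the sorted cells: this difference was larger by 1.29 ± 0.294 for the plastid-encoded mean than for that of nuclear photosynthesis genes, but those genes lay near the floor, with group means of 2.59 to 3.19. A difference between the cell types or their marker lines, which the design does not separate, stays open and untested.

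Ribosomal protein transcripts were higher in cortex cells under salt by a median of 0.68 (adjusted p = 0.274 with an estimated correlation). Matched lists argue against a trend with brightness (percentile 100, with an upper bound of their central range of 0.10). The median was also at percentile 100 among lists matched on expression and gene length, where the upper bound was 0.07. Gene length is not transcript length, so a bias toward short transcripts cannot be decided by this match. The effect on the list mean was 0.64 ± 0.267 (SE) and became 0.952 ± 0.17 with the 3' minus 5' difference as a covariate. The slope of this covariate was shared by all 11 arrays. Pericycle salt replicate 1, with the largest 3' minus 5' differences of all arrays, weighed heavily in it. Its list mean was 6.83, against 7.60 and 7.99 in the other arrays of its group. The fit therefore cannot decide whether RNA quality was the cause in cortex, which stays open. A response of cortex cells to salt remains a hypothesis, found and tested on the same data.

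Root hair markers were lower under salt in cortex and pericycle samples (adjusted p = 0.173 and adjusted p = 0.589 with an estimated correlation), and the pericycle list was not called without pericycle control replicate 1. At least 97.4% of the list median was kept under another scaling, a test that could hardly have come out otherwise. Array medians ran only from 3.41 to 3.58, so scale differences left in the deposited values were too small to give falls of this size. Less root hair RNA in the sorted salt samples may explain the pattern: the 12 falls in cortex, from -2.63 to -0.58, were not shown to differ in size by a chi-square test of heterogeneity (p = 0.212), which is approximate and of little power because all members were measured on the same few arrays. Whether sorting for the marker line's fluorescence removed all root hair cells was not measured. AT4G26010 stood at 8.36 in cortex control samples, a level that does not tell which cells its RNA came from. A fall of these genes in the sorted cells themselves or in the roots under salt stays open and was not tested.

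The 6 arrays compared in cortex can be split into 3 and 3 in 10 ways, which cannot give a share under 0.05. The real split gave 946 probe sets and 9 gene lists and was the only 1 to give as many; the highest of the other splits gave 0 and 8. For pericycle against cortex under salt, 10 splits likewise cannot give such a share: the real split gave 4066 probe sets and 10 lists, as many as 1 split in all, and the highest others gave 0 and 7. Every other split still held unequal numbers of the real groups on its sides, so it kept part of their difference. The lists called by other splits therefore cannot tell whether the preset correlation gives calls without a real difference.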

How the results depend on the processing

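Testing the fixed lists alone was chosen only after the result was seen. The spread limits the counts: the pericycle arrays varied more than the cortex arrays, and the shared estimate lies between them. With only the groups compared, the count for salt was 4487 in cortex and 0 in pericycle (1502 at an unadjusted p under 0.05), and 14 lists were called in cortex. With array weights these counts were 4775 and 32. In cortex all 946 probe sets passed under both settings. With 1 probe set per gene, which tests fewer probe sets, the 5 counts were 458, 203, 72, 1718 and 2017 (salt in cortex, salt in pericycle, difference, cell types without and with salt). With the replicate block, whose numbers the labels do not tie across groups, salt in pericycle gave 194 and the difference 121. Leaving out dim probe sets, either scaling, trend with robust, and a log2 difference of at least 1 left all 5 counts within 1.5 times.

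Leaving out an array in turn gave ranges of 362 to 1701 (salt in cortex), 183 to 1124 (salt in pericycle), 53 to 635 (difference), 2258 to 5007 (cell types without salt) and 2461 to 5102 (with salt). For salt in cortex the counts were 447, 476 and 546 without control replicates 1, 2 and 3, 378, 528 and 362 without salt replicates 1, 2 and 3, and 1701 without pericycle salt replicate 1. For salt in pericycle they were 248, 194 and 234 without cortex control replicates 1, 2 and 3, 192, 183 and 183 without cortex salt replicates 1, 2 and 3, 1124 without pericycle control replicate 1, and 975 and 1084 without pericycle salt replicates 1 and 3. For the difference they were 80, 63 and 101, then 61, 93 and 53 for the same cortex arrays, 635 without pericycle control replicate 1, and 436 and 535 without pericycle salt replicates 1 and 3. For the cell types under salt they were 2461 and 2474 without cortex salt replicates 1 and 3. Where pericycle control replicates were left out, the lone array left was assumed to vary like the other groups.

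With an estimated correlation 0 lists were called in every comparison, against 9, 4, 4, 6 and 10 with the preset value. The fixed lists alone gave 1, 0, 1, 1 and 1, as fewer lists were tested. Without dim probe sets, 2 lists were called for salt in pericycle, 3 for the cell types without salt and 4 with salt. Leaving out an array gave 9 to 12 lists for salt in cortex, 0 (without pericycle control replicate 1) to 5 for salt in pericycle, 2 (without pericycle control replicate 1 or pericycle salt replicate 1) to 6 for the difference, 3 (without pericycle control replicate 2) to 7 for the cell types without salt and 6 (without pericycle salt replicate 3) to 10 with salt. The 9 lists of salt in cortex were called under each alternative they were tested in except the estimated correlation; 8 of them are added lists, which the fixed lists alone leave out, and lists were not tested with a log2 difference of at least 1 or with 1 probe set per gene. The median of the plastid-encoded genes for salt in pericycle ran from 0.79 (without pericycle salt replicate 3) to a reversed -0.012 (without pericycle control replicate 1), and that of the ribosomal proteins between the cell types under salt from 0.49 (without pericycle salt replicate 1) to a reversed -0.034 (without pericycle salt replicate 3). Where no cause is named, the cause was not tested.

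Of 327 named calls none changed sign, 203 passed without any single array and 124 missed the threshold without at least 1; 268 passed with only the groups compared, 284 with array weights and 309 with quantile normalization. Signal over background limits genes with a group near 2.81, whose folds can be understated.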

Other observations

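All families described in this part are in lists that were tested before, and no test here was chosen only after the result was seen. Several families with no shift as a list held members that differed strongly between the cell types. RALFL32, a gene of RALF-like signalling peptides, was higher in pericycle by 3.6 ± 0.415 (log2, SE) without salt and by 3.94 ± 0.372 with it. The tetraspanin genes TET5 (2.82 ± 0.312 and 3.3 ± 0.279) and TET6 (2.60 ± 0.396 and 3.81 ± 0.354) were also higher in pericycle in both conditions, and so was the glutathione transferase gene GSTU18 (2.23 ± 0.494 and 3.65 ± 0.442). Lower in pericycle in both conditions were the calmodulin-like gene CML30 (-2.48 ± 0.323 and -2.36 ± 0.289), PUB22 (-2.83 ± 0.202 and -1.92 ± 0.18), the transcription factor gene WRKY6 (-1.92 ± 0.259 and -1.91 ± 0.232) and the glycosyltransferase gene UGT73B5 (-2.67 ± 0.218 and -2.20 ± 0.195).

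Further single genes changed with salt in cortex cells. RALFL27 and RALFL22 fell by 2.83 ± 0.551 and by 1.45 ± 0.252, and bHLH115, a transcription factor gene of iron homeostasis, fell by 1.5 ± 0.202. GSTU28 fell by 2.03 ± 0.412. Among 47 glycosyltransferase genes, 3 rose and 3 fell, with UGT76E1 at 1.75 ± 0.203 and UGT73D1 at -2.13 ± 0.42, and the list did not shift (median -0.06, adjusted p = 0.358). RALFL27, RALFL22, GSTU28 and UGT73D1 each missed the threshold without at least 1 of the cortex arrays, and GSTU18 did so without salt when cortex control replicate 3 or pericycle control replicate 1 was left out. Of 24 cell division genes none passed for salt in cortex (median 0.20, adjusted p = 0.0745).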
